A study of Mus musculus with 8 samples.

How the data were processed

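Whole mouse embryos at embryonic day 9.5 were collected from crosses of parents heterozygous for K399A in Smo, 4 wild type (WT) and 4 homozygous mutants. Per the labels, each embryo went into its own tube, libraries were made with a TruSeq RNA kit and were sequenced on a NovaSeq instrument. The labels number the samples within each genotype and name no litter, batch or date. The authors deposited a single table of TPM per gene symbol for the 8 embryos. The genome build given by the labels is GRCm38 (mm10), and the aligner, the counting program, the annotation release and the strandedness of counting are not given in the sources used here. The values summed to the same total in each library, over 41709 symbols, of which 17716 were at 0 in every embryo. All 8 columns were matched to a sample by their names, and 0 columns were left over.

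TPM divides each gene's reads by its length and scales each library to the same total, so within a library a gene's values are whole multiples of a step. These steps were used to recover whole read numbers, with merged exon lengths from GENCODE M21 and, where that length did not give whole numbers in all 8 libraries within 0.02 reads, with the smallest length that did. Of 23993 genes with a value, 22468 (93.64%) were whole with the merged exon length, 1520 (6.34%) with another length and 5 were not recovered. On simulated reads, made with the same merged exon lengths, the method returned 99.38% of genes exactly. The simulation does not test whether the deposited values were made with other lengths. Recovered depths were 60.13, 60.74, 60.65 and 60.67 M reads (M, mega) in WT 1 to 4 and 60.46, 60.04, 61.45 and 61.50 M in mutants 1 to 4. Gli1 rested on 1067 to 2788 reads per library and Smo on 13209 to 16726, so that for such genes counting error was small beside the spread between embryos. Gene positions and types were taken from GENCODE M21, which held 38009 of the 41709 symbols (91.1%).

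The following choices were fixed before the data were examined, except where stated. Genes were kept with at least 1 TPM in at least 4 of the 8 embryos (13596 genes). Mutant was compared with WT by limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with empirical Bayes moderation with a trend, genotype as the only term, two-sided tests and a Benjamini-Hochberg adjusted p under 0.05. Count models were not used, since the deposited unit is TPM. Fold changes are on the scale of TPM + 1 and are therefore nearer 0 than ratios of TPM for genes of low level. The 40 gene lists of Hedgehog targets, tissues, membranes, pathways and RNA quality were written beforehand. Of these, 39 were tested with camera at a preset correlation of 0.01 and adjusted over lists, and sex-linked genes served as the check of each embryo's sex. A list is called when its adjusted p is under 0.05. Each list was also tested with camera at an estimated correlation and with fry, and each member's p was adjusted over the list alone. A few list members, among them old symbols of histone genes, were missing from the table and were not analysed here.

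Scores are means of log2(TPM + 1) over a list in each embryo. Scores and principal components were compared by exact permutation tests over all 70 assignments of 4 against 4, two-sided, whose smallest p is 0.0286, and p values of the 5 planned scores were adjusted together. Principal components used the 1000 most variable kept genes. The genes named are Smo and the core Hedgehog targets, then the 5 genes in each direction with the smallest p since none passed the threshold, leaving out unnamed loci (124 of which had an unadjusted p under 0.05), and up to 4 members with the smallest p of each list discussed. Xist and Y-linked genes were named as the check of sex, and any further gene was chosen after its values were seen. Some genes that this rule names are not reported here.

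The fit was tested on simulated data with the spread of the real genes, drawn independently. Of 100 genes changed 1.5-fold 67 were called, of 100 changed 2-fold 86 were called, and 5 unchanged genes were called. Both shifted lists were called, 0 of 30 unshifted lists were called, and with nothing changed 0 genes and 1 of 39 lists were called. Real genes vary together between embryos, so these rates need not hold in the real data.

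Alternatives tried were other pseudocounts, filters and scalings, array weights, no trend, Xist as a covariate, a fold minimum, permutation per gene, leaving out each embryo in turn, lists without shared genes, other forms of the scores and components, and the replicate number as a block. The numbers do not pair embryos: after centring, same-numbered embryos of the 2 genotypes correlated at -0.062, 0.04, -0.19 and -0.25, so the block is no batch correction. Chosen after seeing the data were limma voom on recovered reads, a fit without mutants 3 and 4, whose libraries stood apart, its reverse without mutants 1 and 2 (for the count of genes only), and the yolk sac score as a covariate. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.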

Results

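RNA was sequenced from 8 whole mouse embryos at embryonic day 9.5. Of these, 4 carried only wild-type Smo (WT) and 4 were homozygous for K399A, an amino acid substitution in Smo (mutant). Smo encodes Smoothened, the membrane protein that carries the Hedgehog signal from its receptor Patched towards the GLI transcription factors. Each embryo was its own sample. The embryos came from several litters, and the labels do not say which embryo came from which litter. The deposited table gave TPM, reads scaled by gene length and library total, for 41709 gene symbols, of which 13596 reached 1 TPM in at least 4 embryos and were tested. Between 60.04 and 61.50 M counted reads (M, mega) per library stood behind these values, as recovered from the steps between them. Each group held 2 embryos with Xist, at 22.4 to 91.9 TPM, and 2 with transcripts of Y-linked genes, at a sum of 45.4 to 72.9 TPM.

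The comparison of mutant with WT asked how the transcriptome of the embryo differed when Smoothened carried the substitution, in a study of receptor allostery in Sonic Hedgehog signalling during development. Smo (chromosome 6, 29735503 to 29761365, build GRCm38) was at 140.2 ± 6.29 TPM (SD, n = 4) in WT and 140.7 ± 12.5 TPM (n = 4) in mutants. The 95% confidence interval of its log2 fold change ran from -0.15 to 0.15. An amino acid substitution need not alter transcript level, so this value is no check of the genotype labels.

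The transcripts of the core Hedgehog targets were on average lower in mutants, but none passed the test. Gli1 (chromosome 10, 127329882 to 127341974), a transcription factor and a direct readout of the pathway, was at 28.5 ± 1.91 TPM (SD, n = 4) in WT and 20.6 ± 7.61 TPM in mutants. Its log2 fold change was -0.53 ± 0.24 (SE; limma adjusted p = 0.372; exact permutation p = 0.0857). Gli1 in mutant 3 was at 10.7 TPM, against 19.5 to 28.9 TPM in the other mutants, and without mutant 3 its log2 fold change was -0.26. Ptch1, the main Hedgehog receptor and itself a target, was at 36.2 ± 4.69 TPM in WT and 33.5 ± 7.13 TPM in mutants, and its log2 fold change of -0.12 was -0.011 without mutant 3 and -0.24 without mutant 4. Hhip, which binds and limits Hedgehog ligands, was at 3.03 ± 0.387 and 2.82 ± 0.920 TPM, and its log2 fold change of -0.10 became 0.02 without mutant 3. The mean over the list of 4 core targets on the log2(TPM + 1) scale was 3.77 ± 0.106 in WT and 3.52 ± 0.287 in mutants, and was -0.11 apart without mutant 3 (-0.25 with all embryos; two-sided exact permutation p = 0.143, adjusted over 5 scores 0.286). The smallest p that 4 embryos against 4 allow is 0.0286. As a list, the 4 targets were not called by camera (adjusted p = 0.241).

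**Figure D1:**
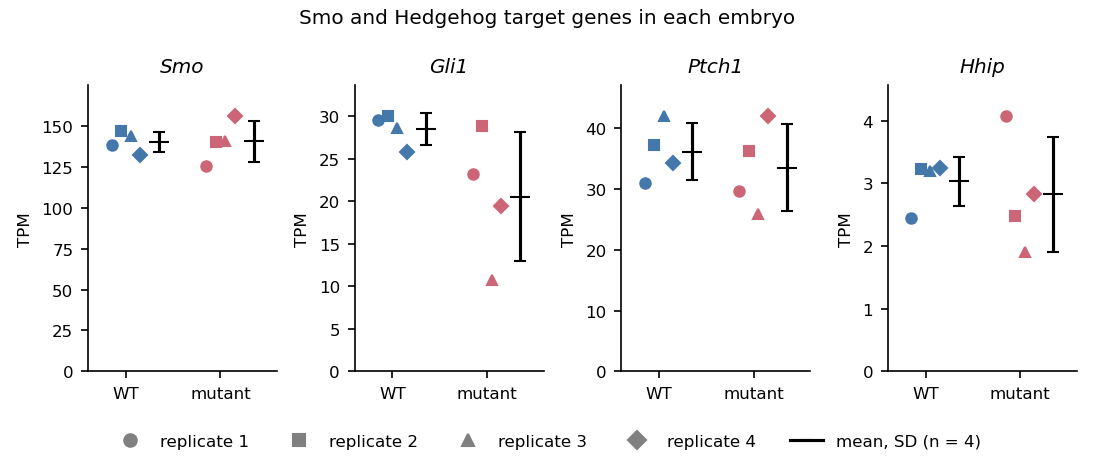
TPM of Smo and of core Hedgehog targets, one point per embryo, with the mean and SD of the 4 embryos of each genotype; each panel has its own axis, which starts at 0. Smo overlapped between the genotypes, and Gli1 was lowest in mutant 3, at 10.7 TPM.

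Regions that Hedgehog patterns were compared by scores of the same kind. The score of ventral neural progenitors and motor neurons, which need Hedgehog, was 2.33 ± 0.284 (SD, n = 4) in WT and 1.87 ± 0.205 in mutants, a difference of -0.46 (exact permutation p = 0.0571, adjusted over 5 scores 0.286). In that list 11 of 12 tested genes were lower in mutants, and the list was called lower (camera adjusted p = 0.00939; adjusted p = 0.482 with an estimated correlation). Nkx2-1, a regulator of the ventral forebrain and of thyroid and lung, passed when adjusted over the list alone, at 6.85 ± 2.04 TPM in WT and 2.98 ± 1.45 TPM in mutants. Olig2, which marks motor neuron progenitors, was at 21.6 ± 5.54 and 11.0 ± 6.23 TPM. Nkx2-2, of the most ventral progenitors, was at 4.00 ± 1.08 and 2.23 ± 0.653 TPM.

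The floor plate and notochord score was 3.43 ± 0.147 in WT and 3.24 ± 0.191 in mutants (difference -0.19, exact permutation p = 0.229, adjusted over 5 scores 0.286), and the list was not called (camera adjusted p = 0.374). Without mutant 3 that difference was -0.10. The dorsal neural score was also lower in mutants, at 3.57 ± 0.191 and 3.31 ± 0.254 (difference -0.26, exact permutation p = 0.229, adjusted 0.286), and -0.17 apart without WT 2. That list was not called (camera adjusted p = 0.0778), but was called lower with median-ratio scaling (adjusted p = 0.0400) and without WT 3 (0.0359), WT 4 (0.0146), mutant 2 (0.0256) or mutant 3 (0.00904). Camera also called it lower with the replicate block (0.0203) and, in a setting chosen after seeing the data, without mutants 3 and 4 (0.0183). The sclerotome, the somite derivative that forms cartilage, had a score of 3.25 ± 0.160 in WT and 3.19 ± 0.250 in mutants (difference -0.06, exact permutation p = 0.743, adjusted 0.743). The sclerotome difference turned positive, to 0.02, without WT 4 or without mutant 1. Its list was not called (camera adjusted p = 0.619), and camera gave the opposite direction to its median log2 fold change of -0.05.

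Across all 13596 genes, limma called 0 genes higher and 0 lower at an adjusted p under 0.05, with a smallest adjusted p of 0.203. An unadjusted p under 0.05 was reached by 1842 genes, 754 higher and 1088 lower in mutants, where 680 are expected by chance. Limma voom on recovered reads, which was chosen after seeing the data, also called 0 genes, and gave 2160 genes at an unadjusted p under 0.05. The exact permutation test per gene called 0 genes too (smallest adjusted p = 0.383). Its smallest possible p of 0.0286 could pass after adjustment only if most genes reached it, so that count decides nothing. The values of the 2 groups did not overlap for 1014 genes (7.46%), against 2.86% by chance. The count at an unadjusted p under 0.05 was 1146 without WT 1, 1203 without WT 2, 3057 without mutant 2 and 3511 with array weights, which still called 0 genes. Without mutant 2 there was 1 gene past the threshold, Gm28230 (log2 fold change -1.52, adjusted p = 0.0325), a gene named after its values were seen. Limma called 3 genes without mutants 3 and 4, and 3365 (282 higher and 3083 lower) without mutants 1 and 2. Both fits were chosen after seeing the data, and mutants 3 and 4 were picked because their libraries stood apart, so neither count is a comparison of the genotypes as such.

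None of the following genes passed the threshold. They are among the genes with the smallest p in each direction, and in each the embryos of the 2 groups did not overlap (exact permutation p = 0.0286, the smallest possible). Higher in mutants was Gata4, a transcription factor of heart and endoderm, at 11.1 ± 2.71 TPM (SD, n = 4) in WT and 27.4 ± 6.71 TPM in mutants, a log2 fold change of 1.22 ± 0.19 (SE). Gata5, which acts in the same tissues, was at 8.85 ± 0.404 and 17.2 ± 3.38 TPM, and Bmp2, a ligand of the BMP pathway, was at 8.46 ± 0.877 and 15.6 ± 2.72 TPM. Atp2a2, the calcium pump of the sarcoplasmic reticulum, was at 209.5 ± 10.8 and 264.8 ± 5.15 TPM, and mt-Nd4, of respiratory complex I, at 1784 ± 141 and 2505 ± 191 TPM. Lower in mutants was Metrn, which encodes the secreted protein meteorin, at 225.5 ± 16.0 and 167.7 ± 13.7 TPM (log2 fold change -0.43 ± 0.07), and Tk1, a thymidine kinase of dividing cells, at 59.8 ± 3.11 and 48.1 ± 1.10 TPM. The non-coding Snhg9 was at 12.8 ± 1.88 and 6.29 ± 1.43 TPM and Epb41l4aos at 122.1 ± 8.93 and 81.4 ± 13.0 TPM. Snhg9 is annotated as antisense and the strandedness of the counts is not stated, so its reads cannot be told from those of an overlapping gene. Snhg9 and Epb41l4aos were each lowest in mutants 3 and 4, whose libraries were low in other small nucleolar RNA host genes, and without these mutants their log2 fold changes were -0.71 and -0.40. The adjusted p was 0.218 for Epb41l4aos and 0.203 for the others.

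**Figure D2:**
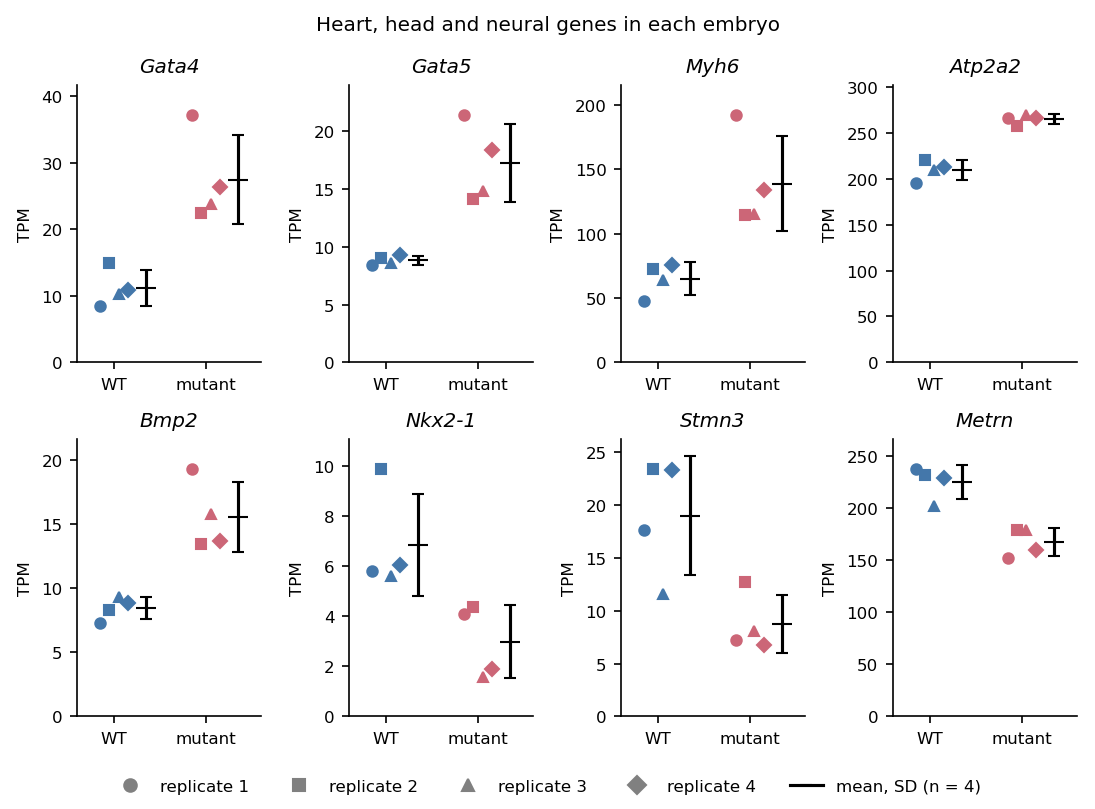
TPM of heart, head and neural genes, one point per embryo, with the mean and SD of the 4 embryos of each genotype; each panel has its own axis, which starts at 0. Gata4 and Myh6 were higher in every mutant than in any WT embryo, and Nkx2-1 was lower.

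Of 39 gene lists tested, camera with a preset correlation of 0.01 called 11 higher and 7 lower in mutants. In settings chosen after seeing the data, it called 7 higher and 13 lower without mutants 3 and 4, and 17 higher and 1 lower with the yolk sac score as a covariate. Without mutant 1 it called 12 higher and 3 lower. With an estimated correlation it called 0 (smallest adjusted p = 0.0835, with 5 lists at an unadjusted p under 0.05). The fry test, which asks whether a list's genes move on balance one way, called 0 (smallest adjusted p = 0.0520, with 8 lists at an unadjusted p under 0.05), and its mixed form, which allows either direction, called 9. Neither form compares a list with other genes. No list held a gene past the threshold over all genes.

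Heart and vessel genes were higher in mutants. Of 22 genes of heart muscle, 19 were higher and 9 were higher when adjusted over the list alone (camera adjusted p = 1.78e-10; adjusted p = 0.456 with an estimated correlation). Myh6, the atrial heavy chain of myosin, was at 65.0 ± 12.7 TPM (SD, n = 4) in WT and 138.8 ± 36.7 TPM in mutants, and Ryr2, the calcium release channel of heart muscle, at 1.16 ± 0.280 and 2.50 ± 0.831 TPM. Of 18 second heart field genes, which mark progenitors added to the forming heart, 14 were higher, 3 of them when adjusted over the list alone (camera adjusted p = 0.000207; adjusted p = 0.456 with an estimated correlation). These 3 were Gata4, Tbx5, at 4.66 ± 1.22 and 8.36 ± 1.71 TPM, and Mef2c, at 4.08 ± 0.416 and 6.47 ± 1.44 TPM. Of 20 endothelial genes, 18 were higher and 12 were higher when adjusted over the list alone (camera adjusted p = 1.22e-10; adjusted p = 0.320 with an estimated correlation). Cdh5, the cadherin of endothelial junctions, was at 42.3 ± 3.67 and 55.7 ± 6.20 TPM, and Kdr, a receptor for VEGF, at 20.8 ± 0.911 and 28.2 ± 4.16 TPM. The mean over both heart lists was highest in mutant 1, at 5.39 against 4.67 to 4.81 in the other mutants and 4.34 to 4.67 in WT, and the difference of 0.33 between genotypes fell to 0.16 without mutant 1. Mutant 1 also had the highest yolk sac endoderm score, 5.39 against 1.09 to 3.36 in WT embryos.

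Transcripts of yolk sac endoderm and of trophoblast and decidua were higher in mutants. All 21 tested genes of yolk sac endoderm were higher, each of them when adjusted over the list alone (camera adjusted p = 3.2e-19; adjusted p = 0.320 with an estimated correlation), with a median log2 fold change of 2.31. Ttr, a carrier of thyroid hormone, was at 10.9 ± 17.7 TPM (SD, n = 4) in WT and 93.2 ± 74.3 TPM in mutants, and Rbp4, the carrier of retinol, at 14.0 ± 18.3 and 96.1 ± 72.4 TPM. The mean over the list on the log2(TPM + 1) scale was 1.09, 1.43, 3.36 and 1.11 in WT 1 to 4 and 5.39, 4.81, 3.32 and 2.52 in mutants 1 to 4 (exact permutation p = 0.0857), so that WT 3 lay above mutants 3 and 4. All 8 tested genes of trophoblast and decidua were higher, none when adjusted over the list alone (camera adjusted p = 6.97e-05; adjusted p = 0.256 with an estimated correlation). Prl8a2, a prolactin family gene of the decidua, was at 7.04 ± 6.80 TPM in WT and 92.6 ± 134 TPM in mutants, with 291 TPM in mutant 2. Hand1, in the same list, also acts in heart and was at 73.2 ± 11.4 and 113.2 ± 37.2 TPM.

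Genes of the forebrain and of neurons were lower in mutants. Of 16 genes of ventral forebrain and eye, 15 were lower, 6 of them when adjusted over the list alone (camera adjusted p = 0.000452; adjusted p = 0.256 with an estimated correlation). Beside Nkx2-1, these included Vax2, of the ventral retina, at 2.02 ± 0.624 TPM (SD, n = 4) in WT and 0.614 ± 0.287 TPM in mutants. Lhx2, of forebrain and eye field, was at 25.1 ± 3.66 and 15.2 ± 4.77 TPM. Of 23 neuronal genes, 22 were lower, 1 of them when adjusted over the list alone (camera adjusted p = 2.87e-06; adjusted p = 0.482 with an estimated correlation). That gene was Stmn3, which binds tubulin, at 19.0 ± 5.63 and 8.71 ± 2.74 TPM; Elavl3, an RNA-binding protein of neurons, was at 10.2 ± 4.71 and 4.39 ± 2.27 TPM. Of 15 neural progenitor genes 14 were lower (camera adjusted p = 0.00939; adjusted p = 0.632 with an estimated correlation), as were 12 of 13 Notch targets (camera adjusted p = 0.00468; adjusted p = 0.456 with an estimated correlation). Hes5, a Notch target that belongs to both lists, was at 85.1 ± 19.4 and 57.8 ± 22.8 TPM. All 15 posterior Hox genes, which pattern the caudal trunk and limb, were lower (camera adjusted p = 0.000833; adjusted p = 0.550 with an estimated correlation), among them Hoxd10, at 21.5 ± 4.32 and 12.2 ± 5.09 TPM. Without mutant 1, progenitors (adjusted p = 0.533), Notch targets (0.0646) and posterior Hox genes (0.203) were no longer called, nor were progenitors (0.0888) and Notch targets (0.106) without the genes they share with other lists. With the yolk sac score as a covariate, a setting chosen after seeing the data, the ventral forebrain and eye list stayed called and neurons (adjusted p = 0.103), ventral neural genes (0.0888), progenitors (0.939), Notch targets (0.565) and posterior Hox genes (0.989) did not.

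**Figure D3:**
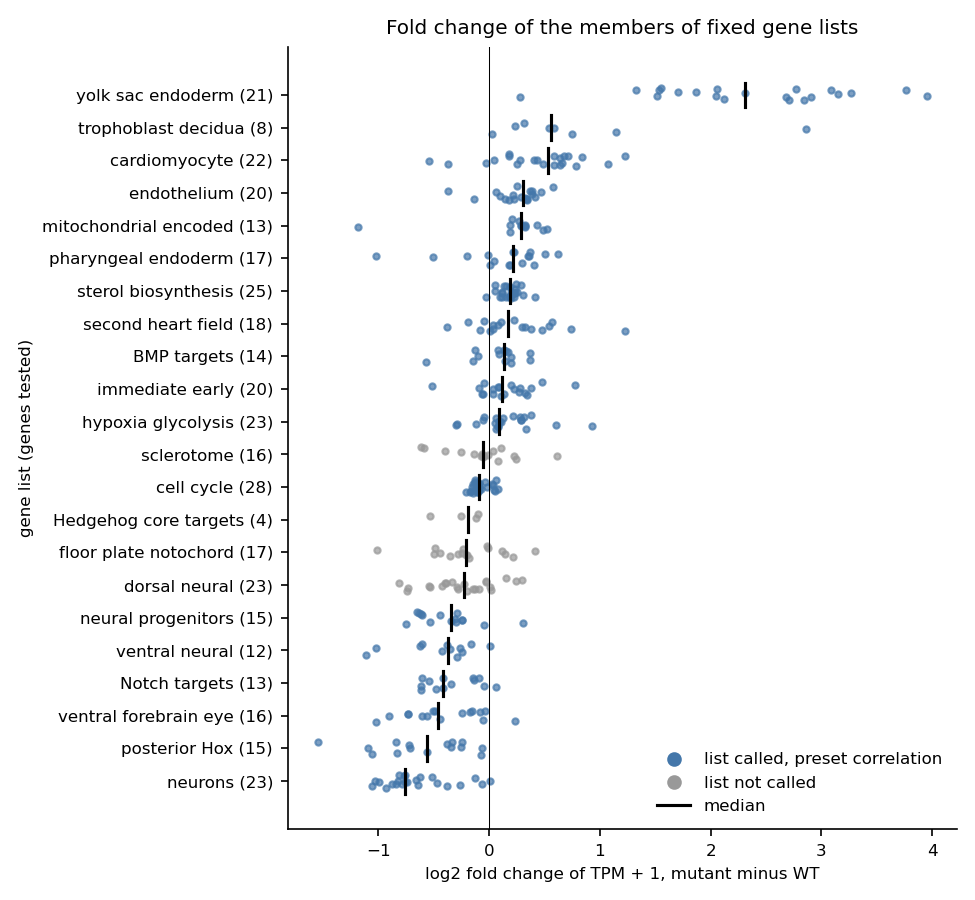
Log2 fold change of TPM + 1, mutant minus WT, of every tested gene in the 18 lists called by camera (blue) and in the 4 lists of scores that were not called (grey); points are genes, bars are list medians, and the number of tested genes follows each name. Yolk sac endoderm had the highest median of these lists, 2.31, and neurons the lowest, -0.76.

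Lists of energy supply and sterol synthesis were called higher in mutants. Of 13 genes encoded in the mitochondrial genome, 12 were higher, 11 of them when adjusted over the list alone (camera adjusted p = 7.05e-12; adjusted p = 0.256 with an estimated correlation), and their share of TPM was 4.70% to 5.45% in WT and 5.90% to 6.66% in mutants. The exception, mt-Nd6, encoded on the other strand, was at 4.06 and 10.8 TPM in mutants 3 and 4 and at 27.9 to 36.2 TPM in the other libraries. Of 23 genes of the hypoxia response and glycolysis, 18 were higher and 4 were higher when adjusted over the list alone (camera adjusted p = 1.85e-05; adjusted p = 0.0835 with an estimated correlation). Adm, which encodes the vascular peptide adrenomedullin, was at 1.94 ± 0.415 TPM (SD, n = 4) in WT and 4.66 ± 1.36 TPM in mutants, and Slc2a1, a glucose transporter, at 478.4 ± 36.9 and 603.2 ± 71.0 TPM. Of 25 genes of sterol synthesis 24 were higher, none when adjusted over the list alone (camera adjusted p = 1.71e-05; adjusted p = 0.625 with an estimated correlation), among them Fdps, which makes farnesyl diphosphate, at 106.6 ± 12.3 and 134.0 ± 30.7 TPM. The sterol score was 5.60 in mutant 3, the lowest of the 8 embryos, 6.18 to 6.33 in the other mutants and 5.66 to 6.05 in WT (exact permutation p = 0.371). Without mutants 3 and 4, a setting chosen after seeing the data, the hypoxia list was no longer called (adjusted p = 0.0747).

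The remaining lists called by camera had no member past the threshold in the list's direction when adjusted over the list alone. Higher in mutants were 15 of 20 immediate early genes (camera adjusted p = 0.00061; adjusted p = 0.229 with an estimated correlation), 13 of 17 pharyngeal endoderm genes (0.00823; adjusted p = 0.524 with an estimated correlation) and 10 of 14 BMP targets (0.0217; adjusted p = 0.550 with an estimated correlation). Nkx2-1, a pharyngeal member past the threshold when adjusted over the list alone, was lower. Smad6, an inhibitor induced by BMP, was at 23.0 ± 1.29 TPM (SD, n = 4) in WT and 30.2 ± 4.37 TPM in mutants. Lower were 22 of 28 cell cycle genes (0.0217; adjusted p = 0.632 with an estimated correlation), by a median log2 fold change of -0.09. The cell cycle call ended with median-ratio scaling (adjusted p = 0.156), without WT 3 (0.0750) and without mutant 1 (0.684). The BMP call ended without WT 2 (0.0683), WT 3 (0.0575), mutant 1 (0.0941) or mutant 3 (0.125), and the pharyngeal call without mutant 1 (0.0874). Without mutants 3 and 4 the immediate early (0.0584), pharyngeal (0.103) and BMP (0.161) calls ended, and with the yolk sac score as a covariate the pharyngeal (0.117) and cell cycle (0.751) calls ended.

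In the principal components of the 1000 most variable genes, the first carried 39.1% of the variance and separated the genotypes, at -10.8 ± 6.48 (SD, n = 4) in WT and 10.8 ± 7.83 in mutants (exact permutation p = 0.0286, the smallest possible). With all tested genes the difference on it was 23.6 (exact permutation p = 0.0571). Yolk sac genes such as Apoa1, Ttr and Afp weighed most on its mutant side, and Hoxd12, Hoxd13 and Olig2 on its WT side. WT 3, the WT embryo with the highest yolk sac score, lay at -1.09 on it and the other WT embryos between -14.7 and -13.3. The second component carried 25.3%, set mutants 3 and 4 (11.5 and 20.5) apart from the other embryos (-9.75 to -0.311), and did not separate the genotypes (exact permutation p = 0.486). Gas5, a host gene of small nucleolar RNAs shown here because its values stood apart, was at 93.4 and 87.8 TPM in mutants 3 and 4 and at 178 to 237 TPM in the other embryos.

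**Figure D4:**
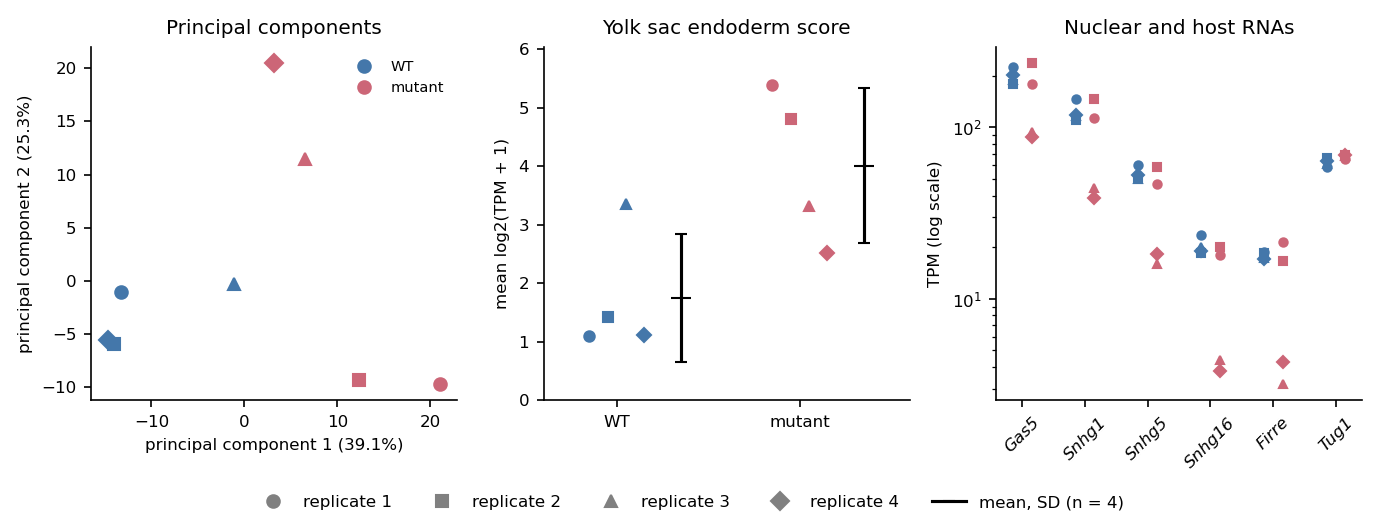
First and second principal components of the 1000 most variable genes, the yolk sac endoderm score on the log2(TPM + 1) scale with the mean and SD of each genotype, and TPM of nuclear and small nucleolar RNA host transcripts on a log axis, one point per embryo. Mutants 3 and 4 stand apart on the second component and in Gas5 (93.4 and 87.8 TPM against 178 to 237 TPM in the others), and WT 3 stands apart from the other WT embryos in the yolk sac score, at 3.36.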

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

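The splits counted at an unadjusted p, the tests of yolk sac genes, the heart test without mutant 1, the test of depth and the host gene medians against WT were chosen only after the result was seen. Samples far from the others of their genotype were sought in 380 groups of 4 values (scores, components, library measures and named genes) by the gap to the nearest other sample over the whole range. A gap above the 95% critical value of Dixon stood out in 24 groups, where chance alone gives about 1 in 20, or 19 groups. Of the 24, 18 were in WT and 6 in mutants, and 8 were in WT 3.

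In WT 3 the values that stood apart were mainly of yolk sac endoderm. The score was 3.36 (1.09 to 1.43 in the other WT embryos), Ttr was at 37.4 TPM (0.763 to 3.86), Rbp4 at 41.3 TPM (3.36 to 8.10), Apob at 8.13 TPM (0.306 to 0.425) and Cubn at 5.06 TPM (0.189 to 0.706). The first principal component of WT 3 was -1.09 (-14.7 to -13.3), Nkx2-6 was at 14.6 TPM (6.81 to 8.07) and mt-Atp8 at 3860 TPM (4150 to 4210).

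Other WT values far from the remaining WT embryos were Hhip in WT 1, at 2.45 TPM (3.20 to 3.25), and the recovered reads of WT 1, at 60.1 M (60.6 to 60.7). In WT 2 they were Cntfr, at 86.3 TPM (60.6 to 65.0), Nkx2-1, at 9.89 TPM (5.62 to 6.07), and the motile cilia score, at 1.48 (1.34 to 1.36). In WT 4 they were the myotome score, at 3.00 (2.58 to 2.58), the immediate early score, at 3.46 (3.48 to 3.49), Ttn, at 1.32 TPM (0.763 to 0.826), Slc2a1, at 423 TPM (494 to 501), and H4c3, at 2.17 TPM (1.55 to 1.64). Among mutants, the neural crest score of mutant 1 was 4.32 (4.01 to 4.03). Mutant 2 had Lfng at 65.5 TPM (43.2 to 45) and Prl8a2 at 291 TPM (7.66 to 49.2), mutant 3 had Barx1 at 33.6 TPM (7.73 to 10.6), and mutant 4 had Id4 at 5.50 TPM (9.37 to 9.63) and Egr1 at 2.72 TPM (2.17 to 2.24).

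Yolk sac endoderm genes were higher in mutants as a list, and Afp, an abundant yolk sac transcript, was at 320, 221, 40.7 and 14.2 TPM in mutants 1 to 4 and at 1.95, 14.6, 51.9 and 4.90 TPM in WT 1 to 4. Yolk sac tissue carried along with some embryos stays open: the members' mean correlation over the 4 WT libraries was 0.93, but WT 3 alone stands apart in the list, so this value restates that and decides nothing. Embryonic endoderm that rose as a whole by as much is argued against, since the 17 tested pharyngeal endoderm genes, none of them in the yolk sac list, had a median log2 fold change of 0.22 ± 0.399 (SD over genes), where 1.16 was the least it needed. A change in the liver bud, which expresses some of these genes, or in the yolk sac itself by genotype was not tested, and the labels describe no removal of the yolk sac. Prl8a2, named above as a gene of the decidua, was at 15.3, 1.20, 9.89 and 1.73 TPM in WT 1 to 4. In mutants 1 to 4 it was at 49.2, 291, 22.2 and 7.66 TPM. Tissue from outside the embryo may thus have come along. However, 1 gene cannot settle that, and WT 1 had the lowest yolk sac score. Of the 22 genes of the yolk sac list, 0 belong to another list.

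Genes of heart muscle and second heart field were higher in mutants, by 0.329 ± 0.188 (SE) on the log2 scale over 39 genes. With the yolk sac score as a covariate the difference was 0.218 ± 0.296, so yolk sac tissue cannot be told apart from genotype here because the standard error is wider than the difference. Without mutant 1 the difference was 0.16 ± 0.0890, so the part that mutant 1 alone might give cannot be settled with 3 mutants. An earlier stage of the mutants was tested by the log2 ratio of Hbb-bh1 to Hbb-y, globins whose balance shifts as primitive red cells mature. The group means differed by -0.0219 ± 0.137 (SE). How far this ratio moves with stage was not measured here. The value therefore sets no limit on a delay, and it does not speak for single embryos. The ratio was 0.32 in mutant 1, the highest of the 8 embryos, and 0.018, -0.2 and -0.18 in mutants 2 to 4. In WT it ran from -0.16 to 0.12, so an earlier stage of mutant 1 stays open. An effect of the genotype on the heart stays open too. Whether an earlier stage bears on the neuronal, neural progenitor, Notch and posterior Hox lists, which were lower in mutants, was not tested.

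Small nucleolar RNA host genes and some nuclear RNAs were low in mutants 3 and 4: of 16 host genes tested, 15 were lowest in these libraries, against 32.67% of all tested genes and 3.571% by chance. Depth is argued against, since recovered reads differed by at most 1.74% from the mean of the others. The genotype as the whole cause is argued against too, since the median log2 difference of the host genes from the WT mean was -0.12 and 0.08 in mutants 1 and 2 and -1.11 and -1.09 in mutants 3 and 4, but a smaller part stays open, as non-coding against coding genes were at 0.0201 and 0.0356 in mutants 1 and 2 and at 0.0651 to 0.14 in WT. Fewer nuclear RNA molecules in these libraries may be a cause, which stays open. Each gene's log2 difference from the mean of the other libraries was taken. Its median over 612 non-coding genes minus that over 12640 coding genes was -0.181 in mutant 3 and -0.216 in mutant 4. Mutant 3 was short of the 0.2 set beforehand, but each of these libraries was in the other's reference, which makes both values smaller in size. Malat1 was at 10.1 and 11.4 TPM in mutants 3 and 4 and at 18.7 to 38.7 TPM in the others, and Meg3 and Firre were low there as well. Tug1, another nuclear RNA, was not low, at 58.8 to 68.9 TPM in all 8 libraries. The mitochondrial mt-Nd6, encoded on the other strand, was low in mutants 3 and 4, at 4.06 and 10.8 TPM. It was at 27.9 to 36.2 TPM in the other libraries. Fewer nuclear RNA molecules alone would not account for that gene. Whether the 2 embryos shared a litter, a handling day or a stage is not given.

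All 35 splits of the 8 embryos into 4 and 4 were compared. For genes past the threshold the real split gave 0, so that all 35 splits must give as many and the count decides nothing; the highest other gave 8. Chance cannot be excluded for the other counts. For an unadjusted p under 0.05, 2 splits, the real one included, gave at least the real 1842 genes, and the highest other had 2079; that other split set WT 1, WT 3, mutant 3 and mutant 4 against the rest. For lists called, 16 splits, the real one included, gave at least the real 18, and the highest other gave 26. Splits that cross the genotypes thus gave counts as large, and why they did was not tested.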

How the results depend on the processing

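The voom fit, the fits without mutants 3 and 4 and without mutants 1 and 2 and the yolk sac covariate were chosen only after the results were seen. Of the values recomputed for the counts, scores and components, 111 stayed the same, 5 counts moved, 2 scores reversed and 1 component lost its p under 0.05. A count stayed the same if it was equal or within a set ratio. For lists only the total was compared. The yolk sac covariate thus counted as the same at 18 lists, although 17 were higher and 1 lower, and 10 were called in the main fit. The fold minimum could give only 0 genes, so its count decides nothing. Scores had to keep their direction and side of the threshold, and components their side. For single genes and lists 804 kept both, while 58 lost a call, 32 gained a call and 57 reversed, most of them lists not called in either fit.

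The cause was not tested for any change given here unless it is named. Leaving out each embryo gave 0 to 1 genes past the threshold, leaving out mutants 3 and 4 gave 3, and leaving out mutants 1 and 2 gave 3365. With an estimated correlation and with fry 0 lists were called. Both allow for genes that vary together. Fry also compares no list with other genes, so its lack of calls cannot be put down to correlation alone. The log2 fold change of Smo ran from -0.0498 to 0.054 without each embryo and was -0.077 without mutants 3 and 4. That of Hhip ran from -0.248 to 0.0203 and was 0.0651. The sclerotome difference ran from -0.172 to 0.0212. On the first principal component the difference with all kept genes was 23.6 (exact permutation p = 0.0571). Without mutants 3 and 4 camera turned lower the Hedgehog mesenchyme targets (adjusted p = 0.0170), sclerotome (0.0107) and integrated stress (0.00127), which it called higher with the yolk sac covariate (0.0102, 0.00117 and 0.00299). It also turned, without a call, Hedgehog components (0.539), limb bud (0.161), neural crest (0.691), primitive blood (0.691), left-right (0.7), WNT (0.482), FGF (0.619) and retinoic acid (0.778) lower and macrophage genes (0.164) higher. The yolk sac covariate turned higher neural progenitors (0.939), posterior Hox (0.989), cell cycle (0.751), allantois and tail bud (0.0117) and ribosomal proteins (0.000287). Mesenchyme targets and limb bud also turned lower with median-ratio scaling (0.690 and 0.744), and the former without shared genes (0.593). With fry, mesenchyme targets (0.786), Hedgehog components (0.912), sclerotome (0.912), limb bud (0.713), neural crest (0.912) and integrated stress (0.912) were lower. Some fits without 1 embryo turned lists that were not called with all embryos, and none that turned a list called it. The following ranges of adjusted p cover every fit without 1 embryo, those that kept the direction included. They were 0.108 to 0.962 for mesenchyme targets, 0.141 to 0.959 for sclerotome, 0.424 to 0.962 for limb bud and 0.504 to 0.959 for macrophages. They were 0.000259 to 0.691 for primitive blood and 0.095 to 0.935 for allantois and tail bud. For integrated stress they were 0.0552 to 0.976 and for ribosomal proteins 0.00157 to 0.614. The fits that turned the list gave 0.269 and 0.691 for primitive blood and 0.275, 0.57 and 0.614 for ribosomal proteins. The replicate block gave 0 genes (smallest adjusted p = 0.277, 1900 at an unadjusted p under 0.05) and 20 lists. Leaving out each embryo gave 15 to 21 lists. At 60.04 to 61.50 M reads per library, depth limits only genes of low level.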

Other observations

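The fits without mutants 3 and 4, without mutants 1 and 2 and with the yolk sac covariate, and the genes named from them, were chosen only after the results were seen. Lists of other tissues and cell types were not called. Of 12 myotome genes, 8 were higher in mutants (camera adjusted p = 0.0643), and Des, the muscle intermediate filament desmin, was higher when adjusted over the list alone, at 38.4 ± 5.96 TPM (SD, n = 4) in WT and 58.5 ± 11.0 TPM in mutants. Of 17 genes of primitive blood 16 were higher (adjusted p = 0.0911), and all 9 genes of motile cilia were lower (0.0911), among them Foxj1, a regulator of ciliated cells, at 6.84 ± 0.690 and 4.92 ± 1.56 TPM. In neural crest (adjusted p = 0.481) Ednra, an endothelin receptor, was higher when adjusted over the list alone, at 14.6 ± 0.282 and 20.2 ± 3.00 TPM. In the limb bud list (0.946) Tbx5, which acts in forelimb and heart, was higher when adjusted over the list alone. Macrophage genes (0.667), allantois and tail bud genes (0.801) and left-right genes (0.504) were not called and held no such member. Camera called the myotome higher without WT 4 (adjusted p = 0.0076), mutant 2 (0.0207) or mutant 4 (0.00769), and primitive blood higher without WT 3 (0.0065), WT 4 (0.000259), mutant 1 (0.0104) or mutant 4 (0.00698). It also called the myotome higher without shared genes (0.042) and primitive blood higher with the replicate block (0.0304). For primitive blood its direction was lower without WT 1 (0.269), mutant 3 (0.691) or mutants 3 and 4 (0.691).

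Among pathways, Hedgehog pathway components were not called (camera adjusted p = 0.458), but Ihh, a Hedgehog ligand made in yolk sac and gut endoderm among other tissues, was higher when adjusted over the list alone, at 0.728 ± 0.223 TPM (SD, n = 4) in WT and 2.07 ± 0.666 TPM in mutants. The yolk sac score was also higher in mutants. Mesenchymal Hedgehog targets were not called (0.946); among them Foxf1 was at 23.9 ± 4.11 and 32.8 ± 12.6 TPM and Barx1 at 29.4 ± 13.7 and 15.4 ± 12.2 TPM. In the lists of mesenchymal targets, pathway components, limb bud and neural crest the direction of camera was higher while the median log2 fold change was below 0. Of 22 genes of p53 and apoptosis 18 were lower (0.144), and Btg2 and Psrc1 were lower when adjusted over the list alone, at 42.3 ± 2.45 and 29.8 ± 6.55 TPM for Btg2. Targets of FGF (0.119), WNT (0.144) and retinoic acid (0.144), the integrated stress response (0.667), ribosomal proteins (0.320) and replication histones (0.431) were not called and held no such member. Camera called WNT targets higher without WT 1 (adjusted p = 0.0212) or mutant 1 (0.00987), and FGF targets higher without WT 3 (0.0402) or mutant 1 (0.00669). It called p53 genes lower without mutant 3 (0.0458), and ribosomal proteins lower without WT 2 (0.0154), mutant 3 (0.00157) or mutant 4 (0.0107). Without mutants 3 and 4 it called lower the ribosomal proteins (3.83e-11), allantois and tail bud (0.000197), mesenchymal Hedgehog targets (0.0170) and integrated stress (0.00127). With the yolk sac covariate it called higher those 4 lists (0.000287, 0.0117, 0.0102 and 0.00299 in the same order), WNT targets (0.00117), FGF targets (0.0102) and retinoic acid (0.0480).

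Without mutants 3 and 4 there were 3 genes past the threshold, all higher in mutants. Gpx3, a secreted glutathione peroxidase, had a log2 fold change of 1.19 (adjusted p = 0.00125) and was at 186 to 206 TPM in WT and at 450, 461, 311 and 267 TPM in mutants 1 to 4. Gsn, the actin-severing protein gelsolin, had a log2 fold change of 1.46 (adjusted p = 0.0115). It was at 5.33 to 6.96 TPM in WT and at 18.7, 19.7, 13.7 and 5.59 TPM in mutants 1 to 4. Prap1 had a log2 fold change of 3.26 (adjusted p = 0.00223). It was at 14.4 and 20.5 TPM in mutants 1 and 2 and at 0.889 and 0.0847 TPM in mutants 3 and 4. With all embryos their adjusted p was 0.245, 0.311 and 0.456 in the same order. Mutants 1 and 2, the mutants left in this fit, had the highest yolk sac scores of the 8 embryos, 5.39 and 4.81. An effect of the genotype on these genes therefore cannot be told apart from tissue carried along. The smallest adjusted p over the other fits, the one without mutants 1 and 2 left aside (0.000315), ran from 0.0325 to 0.564.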
